A study of Homo sapiens with 9 samples.

How the data were processed

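RNA sequencing was deposited for 9 libraries of EPC2, an esophageal epithelial cell line immortalised with telomerase reverse transcriptase. Per the labels, 3 libraries came from cells carrying a non-silencing control and differentiated at the air-liquid interface (ALI, the ALI control libraries). Another 3 came from cells with SPINK7 silenced and differentiated in the same way (the ALI silenced libraries), and 3 came from control cells kept as an undifferentiated monolayer (the monolayer libraries). Per the labels' protocols, ALI cells grew to confluence in medium with 0.09 mM calcium, were moved to 1.8 mM calcium on day 2, were exposed to air on day 7, and were harvested on day 14. The deposited tables of the ALI libraries are named for day 7 at the ALI, which could be counted from air exposure, and number some ALI libraries otherwise than the labels; days, groups and library numbers are those of the labels. The medium held 1 ng/mL epidermal growth factor and 50 ug/mL bovine pituitary extract. Libraries were polyA-selected and stranded, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

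The submitters' processing notes name genome build hg19, STAR 2.4.2a, Bowtie and MACS2, without their roles. The counter, its annotation and its use of strand are not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not be separated. Each deposited table held 29800 transcript rows with coordinates, a read count and an RPKM value per row. The counts were whole numbers and were not normalized in the deposited tables. The RPKM values were made by the authors from larger read totals than the counts sum to, as recovered from counts, RPKM and transcript length, in every library. Rows of the same gene symbol on the same chromosome were summed, which gave 24672 genes. Of the rows, 511 name several genes and held between 0.41 and 0.55% of the counts of a library. No row lacked a gene name, and 1512 rows on alternate contigs held 0% of the counts to 2 decimals. Coordinates are those of the deposited tables (hg19). The reference annotation supplied is of a different build, and none of its coordinates are used here.

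Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, genes kept by filterByExpr on the 3 groups (12806 genes), a robust quasi-likelihood fit over all 9 libraries with 6 residual degrees of freedom, and the quasi-likelihood F-test. The silencing contrast is ALI silenced minus ALI control, and the differentiation contrast is ALI control minus monolayer. Adjusted p-values are Benjamini-Hochberg adjusted within a contrast, with a threshold of 0.05. Standard errors (SE) were derived from the F statistic, and 95% intervals of a log2 fold change use the SE with 6 degrees of freedom. This form of the interval, wider than a normal one, was chosen after the results had been seen. Levels are CPM (counts scaled to the TMM-adjusted library size), as mean ± SD over 3 libraries. Where a group had 0 counts of a gene over its 3 libraries, the fold is a lower bound against a floor of 3 counts over that group. Where it had 1 to 3 counts, the ratio is given with its exact Poisson counting interval, which covers counting error only.

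A total of 27 gene lists (pathways, structures, other cell types and signs of RNA quality) were fixed before the data were examined. The 24 lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over lists within a contrast. The correlation estimated per list and the fry test, which asks whether the members of a list move 1 way on balance, were alternatives. The leukocyte, endothelial and melanocyte lists had 2 tested members each and were not tested as lists. Counts "adjusted over the list alone" apply Benjamini-Hochberg adjustment to the members of that list only.

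The genes named follow a rule fixed before the data were examined. It takes 22 chosen genes in both contrasts. In each contrast it also takes the 8 largest rises and the 8 largest falls in log2 fold change that passed the test, had a mean of at least 5 CPM in the higher group and had no overlap between the CPM of the groups. Finally, it takes up to 4 members that passed the test, with the largest absolute change, from each list described. Some genes that the rule takes are not reported here. Genes outside this rule are said to be chosen after their values were seen. The design, the lists and all alternatives except 3 were also fixed before the data were examined. Chosen after seeing the data were a fit without both ALI libraries numbered 2, a fit with monolayer libraries 2 and 3 summed as 1, and counts thinned to equal depth.

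The alternatives fixed in advance were DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, no low-count filter, a stricter filter (at least 1 CPM and 10 counts in 3 libraries and 50 counts in all), a fit on the 2 groups compared, the replicate number as a block, limma on log2(RPKM + 1) and log2(RPKM + 0.1), limma-voom, an absolute log2 fold change of at least 1, and a fit without each library in turn. Monolayer libraries 2 and 3 differed by less than other pairs, with a chi-square of 1.97 per gene against 18.35 to 175.23 for the other pairs of libraries within a group. That value still exceeds the 1 that sampling noise gives, which does not show that the 2 libraries came from separate cultures. They were kept as separate, and if they are not, the spread used for both contrasts is too low. With them summed as 1, 79 genes passed on silencing against 119, and 3680 for differentiation against 5190.

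The tests were run on simulated counts drawn at the means and library sizes of the real libraries, with 200 genes changed. The changed genes, and the members of the random lists below, were picked among genes with a mean above 5 CPM over the groups. How often changes of lower genes are called was not simulated. For the silencing contrast (12610 genes), edgeR called 11.94% of genes changed 2-fold, 89.55% of those changed 4-fold and 98.48% of those changed 8-fold, and 5% of its calls were false. For the differentiation contrast (12561 genes) the shares were 17.91, 94.03 and 95.45%, with 5.48% false. Of 500 random lists of 30 unchanged genes, camera with the preset correlation gave an unadjusted p under 0.05 for 2% (silencing) and 1.4% (differentiation). With an estimated correlation the shares were 1 and 0.6%, and with fry 5 and 5.4%. The simulation draws genes independently, so it does not test lists whose members vary together. Its shares of false calls likewise leave out shifts that many genes of a library share. Total counts per library ranged from 7641960 to 14009746, so that 3 counts in 1 library corresponded to between 0.214 and 0.393 CPM. Summaries and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.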

Results

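SPINK7 encodes a Kazal-type serine protease inhibitor of squamous epithelium. RNA was sequenced from 3 groups of 3 libraries of EPC2 esophageal epithelial cells to ask which transcripts change when these cells differentiate at an air-liquid interface, and which of them change when SPINK7 is silenced. The ALI control libraries held 7641960, 8740424 and 9863537 counts, the ALI silenced libraries 10962667, 14009746 and 8619938, and the monolayer libraries 12989094, 9617592 and 9034424. The 10 most abundant genes took between 9.53 and 14.56% of the counts of a library. The leading gene was KRT6A in 5 of the ALI libraries, PI3 in ALI control library 2 and FN1 in the 3 monolayer libraries. On the first principal component of log2 CPM, with 71.4% of the variance, the monolayers lay at 109 to 120 and the ALI libraries at -86.6 to -29.4. On the second, with 14.0%, the ALI libraries numbered 2 in both arms lay at -78.5 (control) and -25.5 (silenced), while the other 4 ALI libraries lay at 14.3 to 55.0.

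SPINK7 (chromosome 5, 147691990 to 147695481, plus strand, hg19) was measured in every library first, since it is the silenced gene. Its level was 239 ± 19.4 CPM (SD, n = 3) in the ALI control libraries, at 229, 261 and 225 CPM. It was 30.7 ± 9.00 CPM (n = 3) in the ALI silenced libraries, at 20.9, 38.6 and 32.7 CPM. This was 12.9% of the control level, a log2 fold change of -2.95 (SE 0.30, adjusted p = 0.00246). In the monolayers SPINK7 stood at 0.488 ± 0.267 CPM (n = 3, 15 counts in all), and it was higher in the ALI controls by 8.98 on the log2 scale (SE 0.43, adjusted p = 8.24e-07). Its fall on silencing passed the threshold in all 21 alternatives, with an adjusted p of at most 0.0286.

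**Figure D1:**
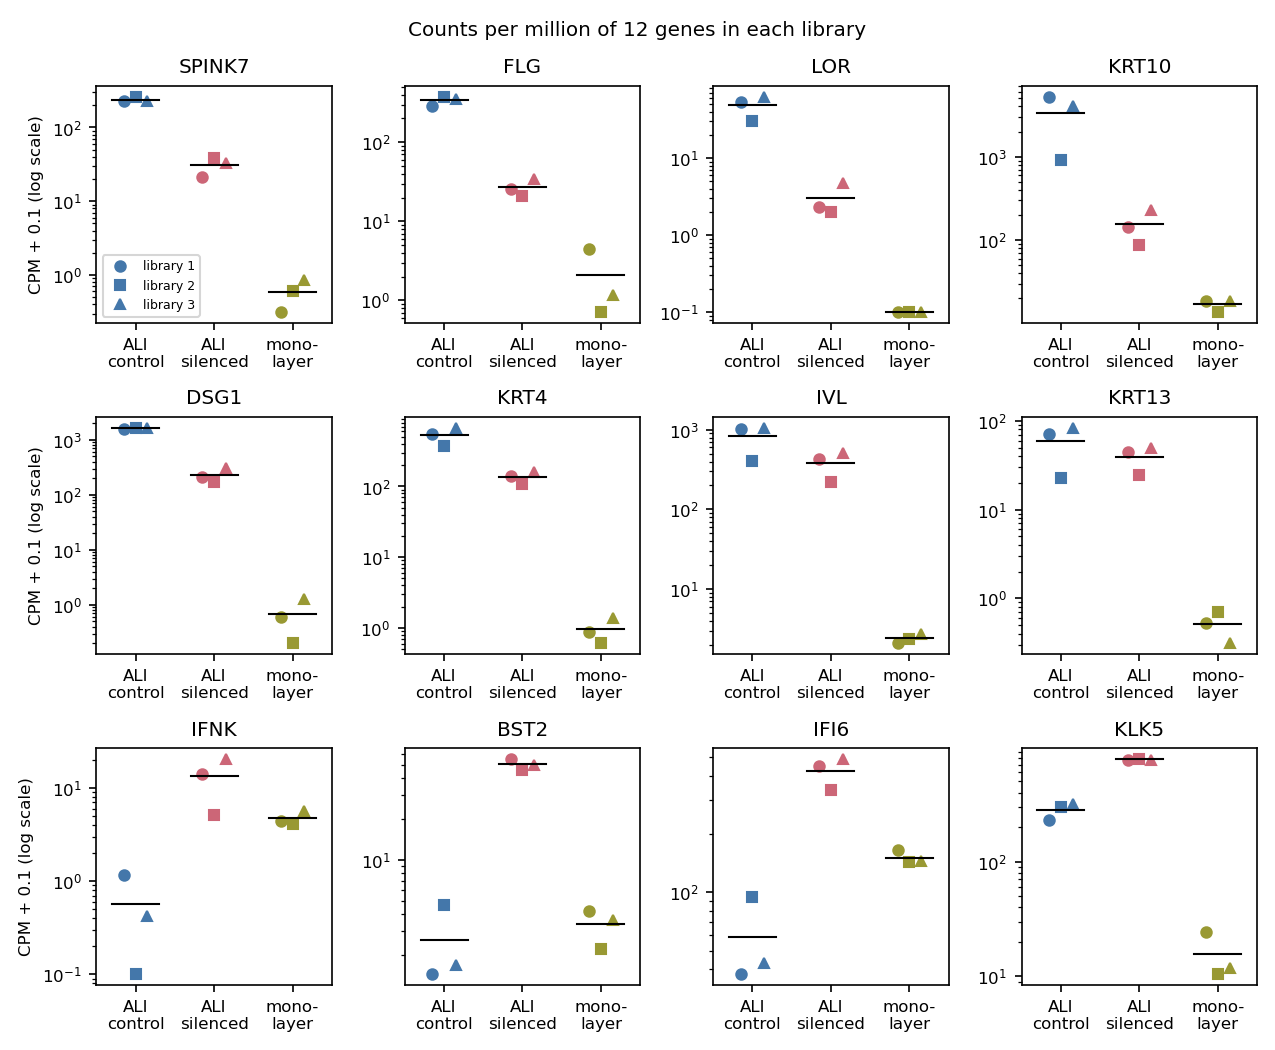
CPM plus 0.1 (log axis) of 12 genes in each of the 9 libraries, by group; symbols give the library number and black lines the group mean. SPINK7 lay at 225 to 261 CPM in the ALI control libraries and at 20.9 to 38.6 CPM in the ALI silenced libraries.

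Genes of squamous differentiation, among them cornified envelope genes, were lower in the silenced libraries. The labels describe no second silenced population. Effects of SPINK7 loss and of the silencing construct therefore cannot be told apart in the silencing contrast. Filaggrin 2 (FLG2; chromosome 1, 152321213 to 152332482), a barrier protein of the outer epidermis, fell from 508 ± 95.1 to 6.61 ± 3.22 CPM (n = 3 each), a log2 fold change of -6.28 (SE 0.41, adjusted p = 0.000308). Filaggrin (FLG; chromosome 1, 152274651 to 152297679) fell from 339 ± 46.3 to 26.8 ± 7.19 CPM, and loricrin (LOR; chromosome 1, 153232179 to 153234600), a main protein of the cornified envelope, from 48.8 ± 16.5 to 2.95 ± 1.51 CPM. The suprabasal keratins KRT1 and KRT10 changed by -5.38 (SE 0.67) and -4.46 (SE 0.64) on the log2 scale, with adjusted p = 0.00593 and 0.0124. The desmosomal cadherins DSC1 (log2 fold change -6.20, adjusted p = 0.00246) and DSG1 (-2.81, adjusted p = 0.0124) fell too, DSG1 from 1604 ± 49.7 to 229 ± 68.1 CPM.

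Among the fixed lists, 11 of 36 tested cornified envelope genes fell and none rose, 18 fell when adjusted over the list alone, and the median log2 fold change was -0.95. The leading members were FLG2, the retroviral-like aspartic protease ASPRV1 (-5.95), KRTDAP (-4.48) and caspase 14 (CASP14, -4.16). The list was lower as a whole (camera adjusted p = 1.67e-20), and this held at adjusted p = 0.0456 with an estimated correlation. Several abundant envelope precursors did not pass. SPRR2A and SPRR2G, small proline-rich proteins chosen after their values were seen, had log2 fold changes of 0.09 and -0.20 (SE 0.30 and 0.36) at 2439 and 2288 CPM in the controls. Involucrin (IVL) gave -1.11 (SE 0.40, adjusted p = 0.331, over alternatives 0.00373 to 0.684), but passed without control library 2 (-1.44, adjusted p = 0.0488) and without both ALI libraries numbered 2 (0.00373). Reads of SPRR2, LCE and keratin genes can be split between near-identical copies. Without silenced library 1 or 3, 7 envelope genes fell in each case, and FLG, KRT10 and DSG1 no longer passed (adjusted p = 0.0779, 0.0780 and 0.0780 without library 1, and 0.0691, 0.0564 and 0.0564 without library 3). Over alternatives these ranged from 5.17e-11 to 0.0779, 3.32e-14 to 0.0780 and 3.21e-17 to 0.0780.

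Genes that build the epidermal lipid barrier were lower too. Of 29 tested, 5 fell and none rose (16 fell adjusted over the list alone), with a median of -1.22 and a camera adjusted p of 1.58e-17, or adjusted p = 0.0403 with an estimated correlation. Those that passed included the phospholipase PLA2G4D (-3.35), the ceramidase ACER1 (-3.18), SDR9C7 (-3.02) and the omega-hydroxylase CYP4F22 (-2.60). PLA2G4D and CYP4F22 lost their calls in 13 and 12 of 21 alternatives (adjusted p from 4.18e-05 to 0.170 and 3.52e-05 to 0.161). Among these were the fits without each single library other than control library 2 (0.0546 to 0.170 and 0.0528 to 0.161). ACER1 lost its call without control library 1 (0.0629) or 3 (0.0523) or silenced library 1 (0.0780), with a range of 1.05e-10 to 0.0780. The count of 5 was 1 without control library 1, control library 3 or silenced library 1, 2 without silenced library 3 or monolayer library 3, and 3 without monolayer library 1 or 2. Of 29 suprabasal and squamous markers 3 fell, namely KRT1, KRT10 and KRT4 (11 fell and 3 rose adjusted over the list alone), with a camera adjusted p of 5.77e-05 but adjusted p = 0.229 with an estimated correlation. The 3 were 1 without silenced library 1 or 3, 5 without silenced library 2 and 6 without control library 2. KRT4, a keratin of esophageal epithelium, went from 537 ± 149 to 136 ± 27.3 CPM (adjusted p = 0.0138), a call lost without control library 1 (0.0629) or 3 (0.0504) or silenced library 1 (0.0832) or 3 (0.0728), with a range of 6.57e-09 to 0.0832. Its esophageal partner KRT13 was at 59.0 ± 32.1 and 39.2 ± 13.1 CPM (log2 fold change -0.60, SE 0.44, adjusted p = 0.728).

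Of 34 protease inhibitors, 2 fell (10 adjusted over the list alone). These were SERPINB12 (-4.87) and SERPINB3 (-3.30), whose reads could be shared with SERPINB4. The list was lower with a camera adjusted p of 1.15e-07, but adjusted p = 0.0935 with an estimated correlation, and 5 of its genes fell without silenced library 2. SPINK5, the inhibitor of epidermal kallikreins, stood at 5586 ± 3603 and 1073 ± 505 CPM and gave -2.38 (SE 0.50, adjusted p = 0.0593, over alternatives 4.18e-05 to 0.235). It passed under 9 of its 21 alternatives: without control library 2 (0.0476), without silenced library 2 (0.0400), without both ALI libraries numbered 2 (0.000580), with DESeq2 (4.18e-05), with the replicate number as a block (0.0117), without the low-count filter (0.0298), with limma-voom (0.0468), and on log2(RPKM + 1) (0.0381) and log2(RPKM + 0.1) (0.0455). Of 23 antimicrobial and S100 genes 3 fell (6 adjusted over the list alone), namely DEFB1 (-3.81), TCN1 (-2.48) and BPIFC (-2.11), with a camera adjusted p of 1.28e-05 but adjusted p = 0.0935 with an estimated correlation. The 3 were 1 without control library 1 or silenced library 1, 0 without silenced library 3 and 5 without control library 2. DEFB1 lost its call without silenced library 3 (0.0885). TCN1 lost it without control library 1 (0.0629) or silenced library 1 (0.130) or 3 (0.131), and in the fit on the 2 ALI groups (0.0576). BPIFC lost it without control library 1 (0.0853) or 3 (0.0697) or silenced library 1 (0.153), 2 (0.0551) or 3 (0.0743). Over 21 alternatives their adjusted p ranged from 2.16e-08 to 0.0885, 6.25e-06 to 0.131 and 2.91e-06 to 0.153.

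Interferon-stimulated genes were higher after silencing. BST2 (tetherin; chromosome 19, 17513755 to 17516384) rose from 2.49 ± 1.78 to 50.5 ± 4.76 CPM, a log2 fold change of 4.34 (SE 0.44, adjusted p = 0.00246). IFI6 (chromosome 1, 27992572 to 27998724) rose from 58.5 ± 31.7 to 426 ± 79.0 CPM (log2 fold change 2.86, SE 0.36, adjusted p = 0.00593). The epithelial type I interferon IFNK (chromosome 9, 27524312 to 27526496) had the largest rise that met the naming rule, from 0.463 ± 0.550 CPM (11 counts in 3 libraries) to 13.3 ± 7.74 CPM, or 4.84 on the log2 scale (SE 0.78, adjusted p = 0.0209). That call was lost without control library 3 (0.107), silenced library 1 (0.0780) or silenced library 3 (0.0942), with a range of 6.06e-09 to 0.107 over alternatives. The call was also lost in the fit on the 2 ALI groups (0.0744) and with limma-voom (0.0544). Of 37 listed interferon-stimulated genes 11 rose and none fell, and 35 rose when adjusted over the list alone, with a median of 1.95. XAF1 (2.31) and the helicase DDX60 (2.29) were the next largest of those that passed. XAF1 lost its call without any 1 control library, silenced library 1 or 3, or monolayer library 2 or 3 (adjusted p from 0.0611 to 0.138; all alternatives 4.79e-06 to 0.138). DDX60 lost it without control or silenced library 1 or 3 (0.0780 to 0.0935; all alternatives 2.10e-07 to 0.0935). In the fit on the 2 ALI groups XAF1 (0.0932) and DDX60 (0.0727) lost their calls too. XAF1 also lost it with monolayer libraries 2 and 3 summed (0.0639). The camera adjusted p was 2.00e-34, but adjusted p = 0.0935 with an estimated correlation. Relative to the ALI control mean, the list's median was 2.47 in silenced library 1, 0.78 in library 2 and 2.398 in library 3. The count of 11 was 32 without silenced library 2 and 33 without both ALI libraries numbered 2. It was 2 without control library 3, silenced library 1 or silenced library 3, 3 without control library 1, 7 without monolayer library 1 and 5 without monolayer library 2 or 3. The antiviral gene MX1, chosen after its values were seen, was at 895, 164 and 853 CPM in those libraries against 76.6 to 142 CPM in the controls (log2 fold change 2.63, adjusted p = 0.0641, over alternatives 6.89e-05 to 0.250). It passed without silenced library 2 (0.00421), without both ALI libraries numbered 2 (0.000108), with DESeq2 (6.89e-05) and with the replicate number as a block (0.0305).

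Other lists and chosen genes showed less. None of 34 cytokines and chemokines passed (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.201), and 1 fell without silenced library 2 or monolayer library 1. The log2 fold changes were -0.51 for TSLP (95% interval -2.51 to 1.48), -0.56 for IL8 (-2.22 to 1.10), 0.01 for IL1B (-0.84 to 0.86) and 0.01 for CSF2 (-1.73 to 1.76). Their directions turned with single libraries, TSLP to 1.27 without control library 2 and IL8 to 0.55 without control library 1, while IL1B ranged from -0.22 (without control library 3) to 0.42 (without control library 2) and CSF2 from -0.65 (without silenced library 1) to 0.65 (without control library 1). None of 16 plasminogen activation genes passed, nor adjusted over the list alone (camera adjusted p = 0.767, median -0.01 and mean 0.03), with PLAU, the urokinase gene, at 198 ± 53.4 and 167 ± 36.6 CPM (-0.24, interval -0.90 to 0.41). Of 40 epithelial proteases 1 fell, trypsinogen PRSS3 (-2.35), and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.201). PRSS3 lost its call without control library 1 (0.0641) or 3 (0.0794) or silenced library 1 (0.0998) or 3 (0.0691), with a range of 4.42e-08 to 0.0998. Without silenced library 2, 5 proteases fell, and without both ALI libraries numbered 2, 11 fell and 1 rose. The kallikrein KLK5 was at 284 ± 46.3 CPM in the controls and 777 ± 10.3 CPM in the silenced libraries, higher in 3 of 3, but its adjusted p was 0.0658 (log2 fold change 1.45, SE 0.32). It passed under 6 of its 21 alternatives (adjusted p from 0.000467 to 0.251), among them the fit without monolayer library 1 (0.0251). The protease list was lower without silenced library 2 (camera adjusted p = 0.00735, over alternatives 0.000953 to 0.766).

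The 13 desmosome genes, 2 of which fell (1 without silenced library 1 or 3), had a median of 0.04 and a mean of -0.61 (2 fell adjusted over the list alone; camera adjusted p = 0.378), and none of 25 tight and adherens junction genes passed (none over the list alone; adjusted p = 0.140, or 0.0344 without control library 1, over alternatives 0.0344 to 0.881). CDH1 gave 0.52 (SE 0.34) and CLDN1 -0.08 (SE 0.55). Basal genes had no member past the threshold and none over the list alone, yet the list was higher (median 0.36, camera adjusted p = 0.0122, adjusted p = 0.529 with an estimated correlation). That call was lost without control library 2 (0.243) or silenced library 1 (0.114), with a range of 0.00380 to 0.529. KRT5 and KRT14 gave 0.48 and 0.06. The NF-kB list (median 0.23) was higher with a camera adjusted p of 0.0270, or adjusted p = 0.656 with an estimated correlation, again with no member past the threshold either way. The NF-kB call was lost without control library 2 (0.949) or silenced library 2 (0.148), with a range of 0.000855 to 0.949. The CAPN14 calpain gene of the esophagus gave -0.43 (SE 0.68, adjusted p = 0.864, over alternatives 0.000253 to 1). It was -2.11 and passed without silenced library 2 (adjusted p = 0.0267), was -2.33 and passed without both ALI libraries numbered 2 (0.000253), and lay at -0.01 and -0.02 without silenced libraries 1 and 3. The 9 tested genes induced by IL-13 or raised in eosinophilic esophagitis had a camera adjusted p of 0.189 (0 past the threshold, 2 fell adjusted over the list alone), or 0.0499 without control library 2 (range 0.0236 to 0.529), and 2 of them fell without silenced library 2. Leaving out silenced library 2 also gave 1 NF-kB gene that rose, and leaving out monolayer library 1 gave 1 basal gene that fell.

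The cell cycle list was higher after silencing (median 1.09, camera adjusted p = 0.0124), with no member past the threshold, none over the list alone, and adjusted p = 0.766 with an estimated correlation. The call was lost without control library 2 (0.806), silenced library 1 (0.583) or silenced library 3 (0.697), with a range of 6.95e-18 to 0.806. Of its genes, 4 rose without silenced library 2 and 20 without both ALI libraries numbered 2. Its genes differed within groups: MKI67 was at 39.6, 0.757 and 42.1 CPM in ALI control libraries 1, 2 and 3, and at 106, 0.893 and 74.8 CPM in the silenced ones. Ribosomal protein genes, a sign of RNA quality or growth state, were lower (median -0.48, camera adjusted p = 0.000581, adjusted p = 0.656 with an estimated correlation; none passed alone or in the list). The test gave adjusted p = 0.867 without ALI control library 2, and ranged from 4.43e-09 to 0.867 over alternatives. The remaining lists did not pass, and none of their members did over all genes. They were cholesterol biosynthesis (adjusted p = 0.767), mesenchymal and matrix (0.378, with 1 higher and 2 lower adjusted over the list alone), glycolysis and hypoxia (0.378, or 0.0196 without silenced library 2, range 0.0196 to 0.861), unfolded protein and integrated stress response (0.378, or 0.00131 without silenced library 2, range 0.00131 to 0.863), fibroblast (0.201), columnar and glandular (0.0694, with 2 higher adjusted over the list alone), replication histone (0.767) and immediate early (0.0754). Of their members, 1 cholesterol gene fell without silenced library 2 and 1 mesenchymal gene rose without control library 2. The immediate early list passed without control library 1 (0.0374), silenced library 2 (0.0197) or monolayer library 1 (0.0158), with a range of 0.0158 to 0.656. Of 12 leukocyte markers the median in the silenced libraries was 0 CPM, and that of 8 endothelial and 7 melanocyte markers was 0.0156 and 0.455 CPM. None of the 2 tested members of each of these 3 lists passed, and 1 endothelial gene fell adjusted over the list alone.

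In all, 29 genes were higher and 90 lower in the silenced libraries at an adjusted p under 0.05 by edgeR's quasi-likelihood test, out of 12806 tested, and 118 of the 119 changed at least 2-fold. These counts moved with the libraries in the fit. They were 3 and 25 without silenced library 1, 92 and 144 without silenced library 2, 5 and 28 without silenced library 3, 8 and 43 without control library 1, 37 and 147 without control library 2, and 6 and 50 without control library 3. Without monolayer library 2 they were 11 and 73, and without monolayer library 3 they were 9 and 69. Of the 40 named genes that passed, 26 lost the call without silenced library 1, 25 without silenced library 3, 20 without control library 1 and 18 without control library 3. Without both ALI libraries numbered 2, they were 280 and 428, with 117 of the 119 genes shared.

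**Figure D2:**
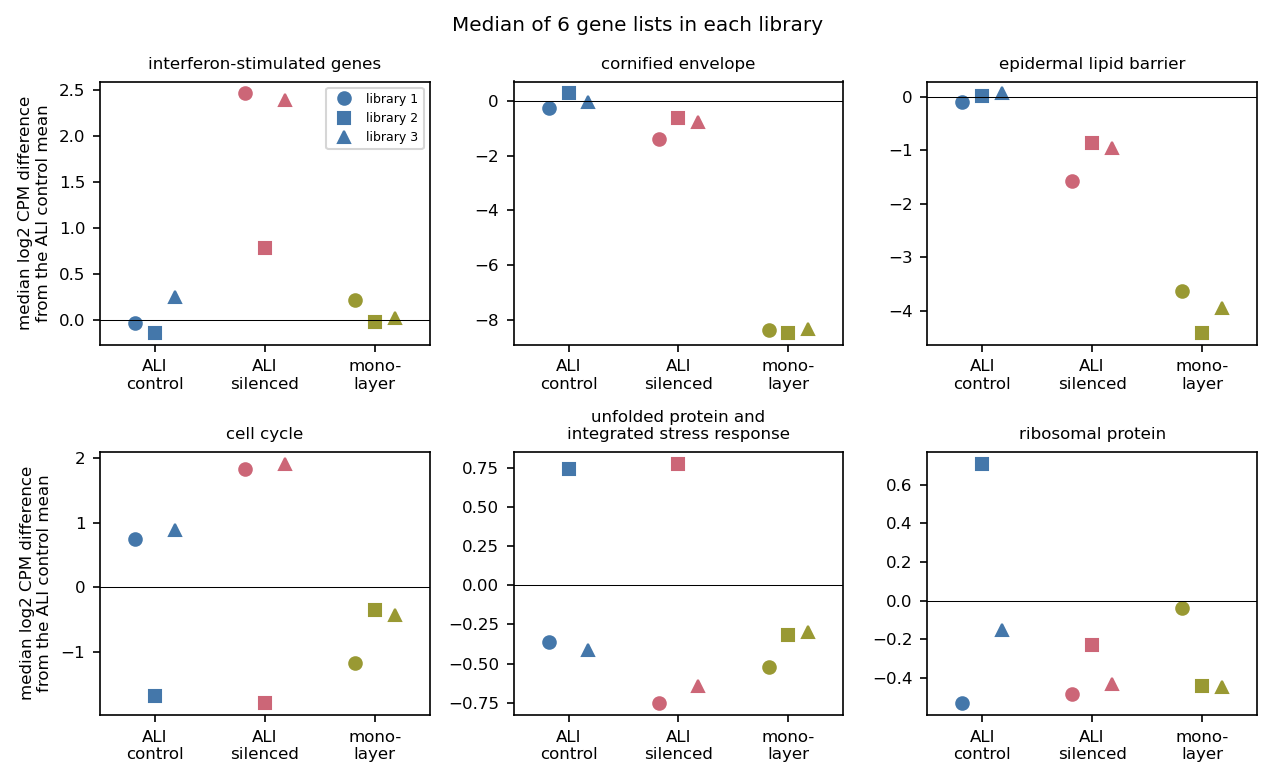
Median difference of log2 CPM from the ALI control mean for 6 gene lists in each library, by group; symbols give the library number. The interferon-stimulated median was 2.47 in silenced library 1 and 0.78 in silenced library 2, and the cell cycle median was -1.68 and -1.79 in ALI control and silenced libraries numbered 2.

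**Figure D3:**
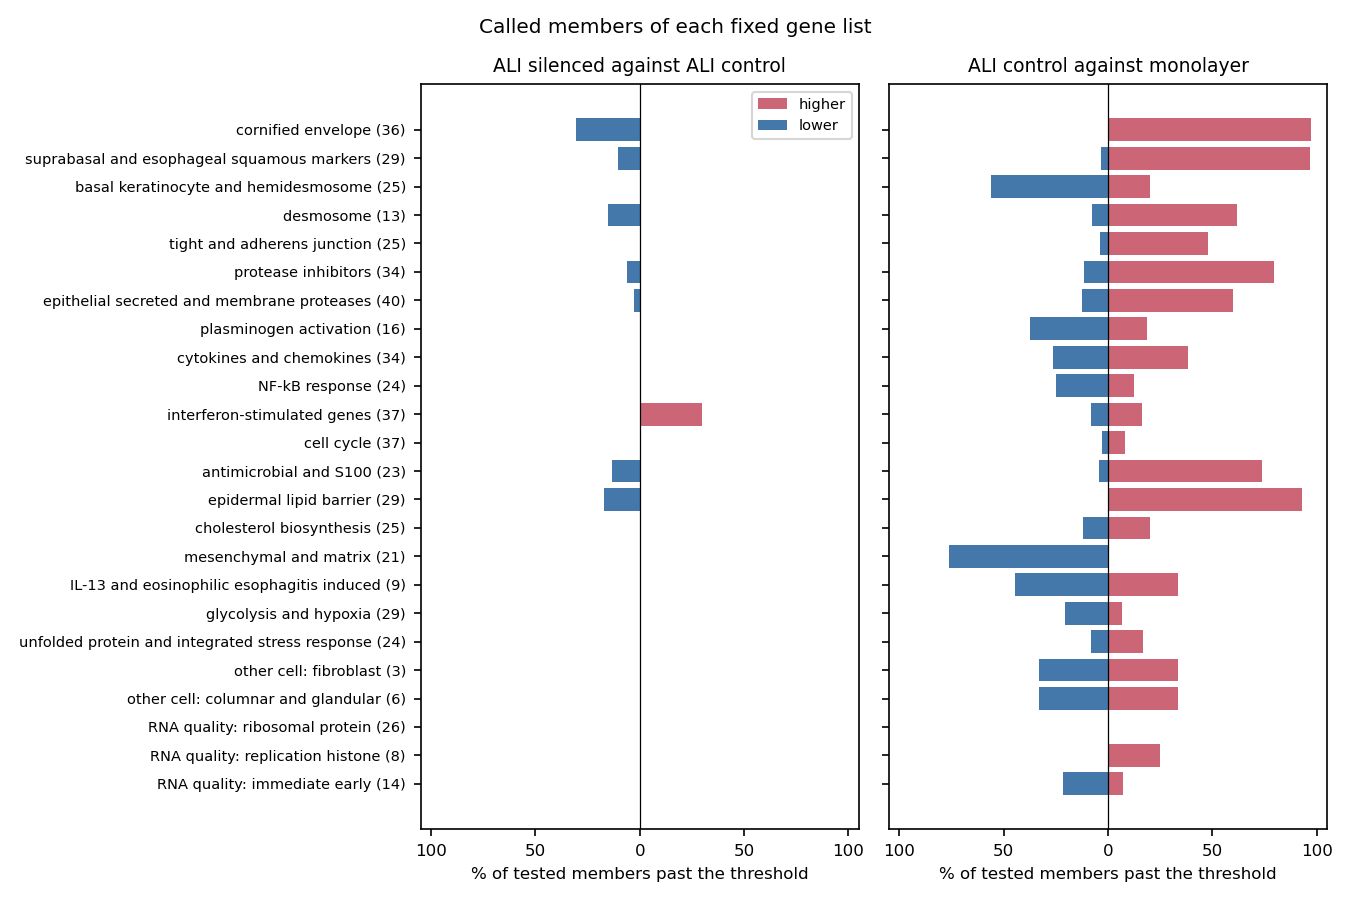
Share of the tested members of each fixed list (number in brackets) that passed the threshold, higher to the right and lower to the left, for silencing (left) and differentiation (right). On silencing, 11 of 37 interferon-stimulated genes were higher and 11 of 36 cornified envelope genes lower.

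Far more genes differed between the ALI controls and the monolayers, the differentiation contrast. The labels give no calcium level or harvest day for the monolayers. Effects of calcium, air exposure and culture time cannot be told apart in this contrast. The protease inhibitor WFDC12 (chromosome 20, 43752067 to 43753106) had 0 counts in the monolayers and 575 ± 150 CPM in the ALI controls, at least 6397-fold higher. FLG2 had 1 monolayer count, a ratio of 16968 (counting interval 3045 to 670196), and KPRP, an epidermal differentiation gene, was at least 1469-fold higher. DSG1 went from 0.589 ± 0.541 to 1604 ± 49.7 CPM (log2 fold change 11.41, SE 0.61, adjusted p = 1.25e-06), and KRT10 from 16.9 ± 2.86 to 3386 ± 2222 CPM (7.65, SE 0.74). Fibronectin (FN1; chromosome 2, 216225179 to 216300791), the most abundant monolayer transcript, went from 47693 ± 3986 to 369 ± 122 CPM (-7.01, SE 0.47, adjusted p = 4.41e-06). The growth factor GDNF had 0 counts in the ALI controls, at least 125-fold lower than in the monolayers.

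Of 36 cornified envelope genes 35 rose (35 adjusted over the list alone), with a median log2 fold change of 10.10, or 9.62 with 5 members at their bound. Suprabasal markers (28 of 29 rose, 1 fell, the same adjusted over the list alone), lipid barrier genes (27 of 29 rose, the same over the list alone), protease inhibitors (27 of 34 rose, 4 fell, the same over the list alone) and antimicrobial genes (17 of 23 rose, 1 fell; 18 and 1 over the list alone) were higher too. The antimicrobial gene that fell lost its call without each single library other than silenced library 2. Their medians were 7.25, 4.43, 4.93 and 6.70 (7.10, 4.43, 4.48 and 6.70 with members at their bound), and camera adjusted p was at most 4.06e-12 for these 5 lists. All 5 held at adjusted p = 0.0149 with an estimated correlation. Examples were HOPX (11.12), PI3 or elafin (11.62), SLPI (10.60), S100A7 (11.74) and PLA2G4E (10.25).

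Epithelial proteases (24 of 40 rose, 5 fell; 25 and 5 adjusted over the list alone), desmosome genes (8 of 13 rose, 1 fell; 10 and 1 over the list alone) and tight and adherens junction genes (12 of 25 rose, 1 fell; 12 and 2 over the list alone) were higher with camera adjusted p = 2.68e-08, 9.05e-05 and 0.00905. With an estimated correlation these became adjusted p = 0.148, 0.186 and 0.461. The tight junction gene CLDN4 (6.57) and KLK5 (4.19) were among them, and CLDN1 rose by 5.70. Mesenchymal and matrix genes fell in 16 of 21 cases and rose in none (17 over the list alone), with a median of -2.39 and camera adjusted p = 2.68e-08, but adjusted p = 0.0929 with an estimated correlation. N-cadherin (CDH2, -5.81), LOXL2 (-4.25) and vimentin (VIM, -4.11) were examples. Basal and hemidesmosome genes fell in 14 of 25 cases and rose in 5 (15 and 5 over the list alone; camera adjusted p = 0.00400, adjusted p = 0.461 with an estimated correlation), among them COL7A1 (-3.15) and PDPN (-3.08). The 5 basal genes that rose were 3 without any 1 of the monolayer libraries, and the 1 junction gene that fell was 2 without control library 3. KRT14 was higher by 1.32 (SE 0.43, adjusted p = 0.0325). That call was lost under 9 of its 21 alternatives (adjusted p from 0.000201 to 0.113), among them the fits without control library 1 (0.0653) or 3 (0.113), silenced library 3 (0.0513), or monolayer library 1 (0.0890), 2 (0.0898) or 3 (0.0930). KRT5 did not pass (0.17, SE 0.42).

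The other lists did not pass with camera in this contrast. Cytokines and chemokines included 13 genes that rose and 9 that fell (13 and 10 adjusted over the list alone; camera adjusted p = 0.684), with IL36A (7.46) and IL36G (7.30) higher. Of 16 plasminogen activation genes 3 rose and 6 fell (the same over the list alone; adjusted p = 0.668), with PLAU (-2.69) lower and SERPINB2 (5.49) higher. Interferon-stimulated genes (6 rose, 3 fell; 6 and 2 over the list alone) had an adjusted p of 0.860, a median of -0.12 and a mean of 0.19, although RSAD2 (4.77) rose. For NF-kB response (3 rose, 6 fell, the same over the list alone), unfolded protein and integrated stress response (4 and 2; none over the list alone) and plasminogen activation the adjusted p was 0.668. It was 0.306 for cell cycle (3 and 1; none over the list alone), or 0.0245 without control library 2 (range 9.57e-07 to 0.913). It was 0.524 for cholesterol biosynthesis (5 and 3, the same over the list alone) and 0.276 for glycolysis and hypoxia (2 and 6; 2 and 5). It was 0.684 for the IL-13 list, whose median of -1.13 and mean of 0.90 differ in sign (3 and 4, the same over the list alone). Fibroblast (1 and 1; 1 and 2 over the list alone; 0.668), columnar and glandular (2 and 2; 3 and 2; 0.860), ribosomal protein (0 and 0; 0.317, or 0.0119 without control library 1, range 0.0119 to 0.913), replication histone (2 and 0, the same over the list alone; 0.219) and immediate early (1 and 3; 1 and 2; 0.773) lists did not pass either. Of the 2 tested members of each, 1 endothelial gene rose (1 over the list alone) and no leukocyte or melanocyte gene passed (1 and 1, and 2 and 0 over the list alone). In the columnar and glandular list the keratins KRT8 (-2.92) and KRT19 (-2.63) fell.

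These counts for the lists that did not pass moved when 1 library was left out. Plasminogen falls (6) were 3 without monolayer library 2 or 3. Interferon falls (3) were 1 without control library 1 or monolayer library 1 or 3, and 6 without silenced library 2. Cell cycle rises (3) were 8 without silenced library 2, 1 without control library 2, silenced library 1 or monolayer library 3, and 0 without control library 3 or monolayer library 1 or 2. Without both ALI libraries numbered 2 these rises were 29. The cell cycle fall was lost without control library 1 or 2 or any 1 monolayer library. Unfolded protein and integrated stress response rises (4) were 0 without control library 2 or any 1 monolayer library, and its falls (2) were 0 without control library 1 and 1 without monolayer library 2 or 3. Cholesterol rises (5) were 3 without any 1 monolayer library, and its falls (3) were 5 without control library 2. IL-13 falls (4) were 2 without control library 3 or silenced library 3, and 1 without monolayer library 2 or 3. Glycolysis rises (2) were 4 without control library 2, and the fibroblast rise was lost without control library 1 or 2 or monolayer library 2 or 3. Replication histone rises (2) were 4 without silenced library 2 and 1 without monolayer library 2 or 3, and immediate early rises (1) were 4 without control library 2 and 2 without monolayer library 1. A ribosomal protein gene rose without control library 1. A leukocyte gene rose without silenced library 2 and 1 fell without control library 1 or silenced library 2, and a melanocyte gene rose without control library 2 or 3 or monolayer library 1.

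In total 2601 genes were higher and 2589 lower in the ALI controls than in the monolayers, and 3813 of the 5190 changed at least 2-fold. With the close monolayer libraries 2 and 3 summed as 1, the counts were 1775 and 1905. They were 1965 and 1988 without monolayer library 1, 1738 and 1842 without library 2, and 1791 and 1890 without library 3. With limma on log2(RPKM + 1) the split was 1928 higher and 3372 lower, and on log2(RPKM + 0.1) it was 1989 and 3306, with the median over all tested genes shifted to -0.13 and -0.18 against 0.03 in the edgeR fit.

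Genes lowered by silencing were mostly genes that differentiation had raised. Of the 90 genes that fell, 76 (84.4%) were higher in the ALI controls than in the monolayers, where independent lists of these sizes would share 18.3. Of the 29 that rose, 17 were among the genes lowered by differentiation, against 5.86 for independent lists, and 1 was among those raised. Both contrasts use the ALI control libraries. Simulated silenced libraries with no effect gave overlaps of 0.05 and 0.1 genes on average, with a maximum of 1 for each over 20 draws. On average 0.3 genes passed on silencing in these draws, so they do not show how much of the overlap the shared controls bring. The 3 control libraries cannot be divided into 2 sets of 2, so part of the excess may come from sharing them. Over genes, which are not independent replicates, the covariance of the log2 fold changes was -0.49 (correlation -0.50), against -0.09 (-0.13) in the simulation with no silencing effect, a difference of covariances of -0.40. By the spread of the 3 control libraries, sharing them would add -0.12. Neither value bounds what sharing brings, since many genes of a control library can move together. Leaving out 1 library gave overlaps of 24 to 128 for the genes that fell and 2 to 44 for those that rose, with 24 and 2 without silenced library 1 and 128 and 44 without silenced library 2. The others that moved them were control library 1 (39 and 6), control library 2 (123 and 18), control library 3 (44 and 4), silenced library 3 (25 and 4), and monolayer libraries 1 (69 and 9), 2 (63 and 7) and 3 (59 and 4). Of all genes raised by differentiation, 2.92% fell on silencing.

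**Figure D4:**
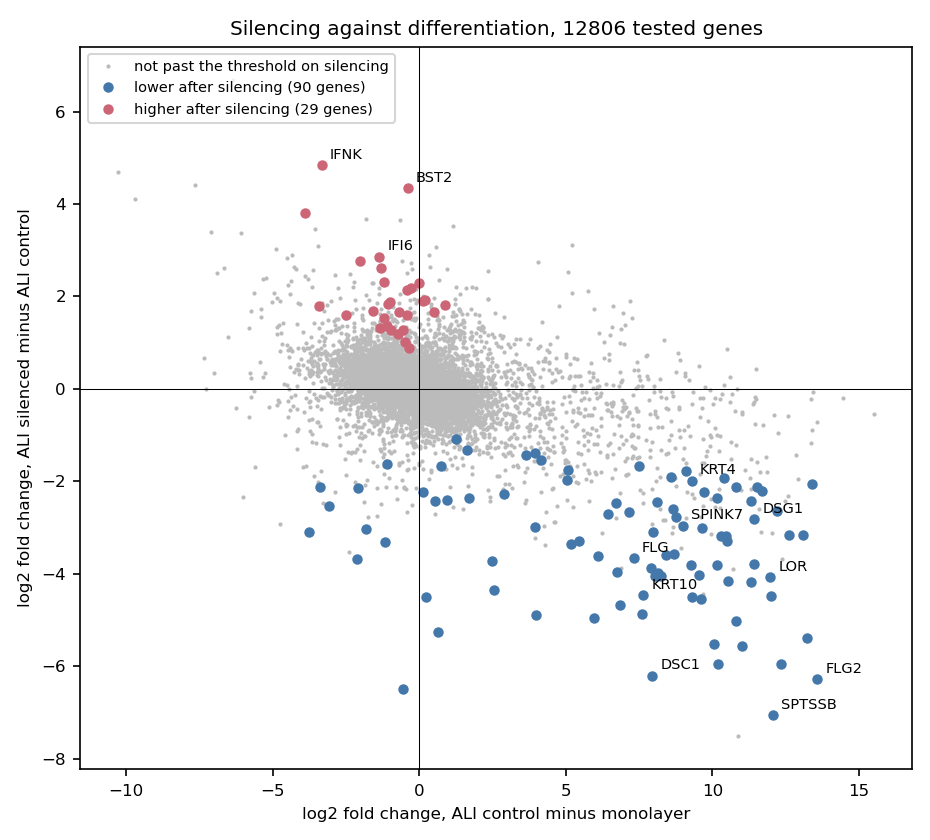
Log2 fold change on silencing (vertical) against that on differentiation (horizontal) for each of the 12806 tested genes; coloured points passed the silencing test. Of the 90 lower genes (blue) 76 had been raised by differentiation, while BST2 (4.34) and IFNK (4.84) lie at the top.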

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

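The fits without both ALI libraries numbered 2, with monolayer libraries 2 and 3 summed, and with counts thinned to equal depth were chosen only after the results were seen; the other settings were fixed beforehand. SPINK7 kept its fall in every setting run, between -3.17 and -2.74 with 1 library left out. Of the 29 higher and 90 lower genes on silencing, DESeq2 gave 140 and 275, the fit on 2 groups 5 and 54, and the fit without both ALI libraries numbered 2 280 and 428. The higher count was 45 without the low-count filter, 52 on log2(RPKM + 1), 46 on log2(RPKM + 0.1) and 9 with the monolayer libraries summed. With 1 library left out the counts ranged from 3 to 92 and from 25 to 147. The genes raised by differentiation that fell on silencing (76) were 221 with DESeq2, 116 on log2(RPKM + 1) and 353 without both ALI libraries numbered 2, and ranged from 24 to 128 with 1 library left out. Those lowered that rose (17) were 70 with DESeq2, 3 on 2 groups, 102 without both ALI libraries numbered 2 and 5 with the monolayers summed, and ranged from 2 to 44. Of 10 gene lists called on silencing, 2 held with an estimated correlation, and fry called 6 lists, among them the columnar and glandular list, which camera did not call. Of 10 called for differentiation, 5 held with an estimated correlation, and fry called 12, these 10 and, as higher, cholesterol biosynthesis (adjusted p = 0.0435, over alternatives 0.0435 to 0.879) and the IL-13 list (0.0174, over alternatives 0.0174 to 0.913), which camera did not call. The NF-kB list turned from higher to lower without both ALI libraries numbered 2 (adjusted p = 0.888, over alternatives 0.000855 to 0.949). The interferon-stimulated genes that rose (11) were 34 with DESeq2, 21 with the replicate number as a block, 18 without the low-count filter, 2 on 2 groups and 5 with the monolayers summed. The lipid barrier genes that fell (5) were 13 with DESeq2, 8 without the low-count filter, 2 on 2 groups, on log2(RPKM + 0.1) or with the monolayers summed, and 17 without both ALI libraries numbered 2. With DESeq2 8 suprabasal markers, 8 protease inhibitors and 5 antimicrobial genes fell, against 3, 2 and 3. Without both ALI libraries numbered 2 these counts were 14, 10 and 8, and 19 cornified envelope genes fell against 11. With the replicate number as a block, 6 suprabasal markers and 5 protease inhibitors fell. Fewer libraries or groups leave fewer degrees of freedom; beyond that the cause was not tested. Of the values for named genes, 3535 kept their side of the threshold, 299 lost it, 47 gained it and 0 that passed in either fit reversed. In another 50 the sign turned while neither fit passed; these count as kept. At these depths 3 counts correspond to 0.214 to 0.393 CPM, which limits low genes.

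With the replicate number as a block, 51 genes were higher and 125 lower on silencing. Deviations of same-numbered ALI control and silenced libraries from their group means correlated at 0.49, 0.58 and -0.01. ALI control library 3 correlated best with silenced library 1 (0.64). Deviations from a mean of 3 libraries are tied to each other, so these values cannot show whether the label numbers pair the libraries. By the other numbering in the names of the deposited tables, only 2 pairs share a number, control 1 with silenced 3 (0.21) and control 2 with silenced 2 (0.58), too few to decide.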

Other observations

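The tests below were chosen only after the patterns were seen, and for those of transcript length and of read depth the outcome was not yet known. Outside the fixed lists and the 22 chosen genes, 80 of the 119 genes that changed on silencing were found, 18 higher and 62 lower. Among the higher were HLA-B and HLA-C, antigen-presenting molecules chosen after their values were seen. They rose by 1.54 and 1.27 on the log2 scale (adjusted p = 0.0237 and 0.0411), HLA-B from 136 ± 11.1 to 395 ± 90.2 CPM (n = 3 each). Both are near-identical copies that can share reads. HLA-B lost its call without control library 1 (0.126) or 3 (0.0886), silenced library 1 (0.0862) or 3 (0.0691) or monolayer library 3 (0.0576), and HLA-C without each single library other than control library 2 (0.0620 to 0.166). Both lost it in the fit on the 2 ALI groups (0.0665 and 0.134) and with monolayer libraries 2 and 3 summed (0.0521 and 0.0863). Over 21 alternatives their adjusted p ranged from 3.93e-06 to 0.126 and from 0.000148 to 0.166. ALDH1A3, a retinaldehyde dehydrogenase, also chosen after its values were seen, rose from 729 ± 209 to 2736 ± 271 CPM (1.91, adjusted p = 0.0367). ALDH1A3 lost its call in 8 of 21 alternatives (adjusted p from 3.05e-06 to 0.146), among them the fits without control library 1 (0.0727) or 3 (0.139), silenced library 1 (0.126) or 3 (0.146), or monolayer library 2 (0.0657) or 3 (0.0705). SPTSSB, a subunit of the enzyme that starts sphingolipid synthesis, had the largest fall that met the naming rule (-7.05, SE 1.15, adjusted p = 0.0375). It varied in the ALI controls (52.7 ± 64.8 CPM), and SPTSSB lost its call in 6 of 21 alternatives (adjusted p from 1.55e-06 to 0.172), among them the fits without control library 1 (0.0727) or silenced library 1 (0.172), 2 (0.0752) or 3 (0.171).

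The interferon-stimulated genes were higher in each silenced library, but less so in library 2. The rise did not rest on 1 silenced library: with any of them left out, the list's median difference was at least 1.62. Leukocytes in the cultures are argued against by a median of 0 CPM over 12 leukocyte markers in the silenced libraries, with CD14 highest at 3.03 CPM against 4.69 CPM in the controls. The IFNK transcript level alone stays open: IFNK was also higher in the monolayers (4.63 CPM) than in the ALI controls, where the list's median difference was -0.12 (bootstrap interval -0.35 to 0.18), but its members went both ways (16 higher and 21 lower in the ALI controls, IFI6 at -1.37) and differentiation differs there too. A response to the silencing construct itself may underlie the rise; it was not tested and stays open.

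The ALI libraries numbered 2 stood apart in both arms, with cell cycle medians at -2.52 (control) and -3.67 (silenced) relative to the other libraries of their group. Their unfolded protein and integrated stress response medians lay at 1.11 and 1.30, with ASNS, a stress-induced amino acid enzyme chosen after its values were seen, at 739 and 479 CPM against 54.2 to 116 CPM in the other ALI libraries. Lists fixed as signs of RNA quality, which growth state could also change, moved too. Replication histones moved by 1.27 in the control library (7 of 8 genes highest of the group) and upward in the silenced library (8 of 8). Ribosomal protein genes moved by 1.06 (26 of 26) and 0.24 (18 of 26). Transcript length is argued against, since the cell cycle medians were -2.36 and -3.67 against genes of the same length (83.8% of the list had one), as is read depth, with -2.64 and -3.50 after thinning, and a swap between the ALI groups by SPINK7, whose level in control library 2 was 6.76 times that of the highest silenced library. A difference in culture, harvest or RNA quality shared by both libraries could account for the pattern, but the labels name none and it stays open.

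Genes raised by differentiation had uneven log2 fold changes on silencing. Over 402 genes raised at least 16-fold, with a mean of at least 5 CPM in the ALI controls, the median was -1.01 (SD 1.49), and 68 lay above 0. A lower share of equally differentiated cells as the only change, which would lower all these genes alike, is argued against. Such a lower share together with another change is not addressed. The mean squared deviation of these changes was 9.40 times their mean squared error (bootstrap interval 7.73 to 11.1, over genes that are not independent). A loss of only some of the differentiated cells could lower genes unevenly, so it is not addressed by this ratio. A delay that lowers late genes more than early ones was not tested and stays open. Shared control libraries as the whole cause stay open. The covariance between the contrasts was -0.49, and ranged from -0.63 to -0.38 with 1 library left out. It lay below the -0.12 given by the spread of the control libraries and the simulated -0.0993 to -0.0755. The simulation draws genes independently, whereas many genes of a control library moved together. Neither value therefore bounds what sharing the controls brings. Whether falls cluster in the epidermal differentiation complex on chromosome 1 (151955386 to 153604513, hg19) stays open, since the region was picked after genes in it were seen to fall: 11 of 45 raised genes inside fell against 65 of 2556 outside (odds ratio 12.4, 5.40 to 26.4).

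The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. On silencing 1 of 10 splits, the real one, gave 119 genes and the highest other gave 0, and for differentiation 1 of 10 gave 5190 and the highest other 0. Each other split puts libraries of both conditions in 1 group, which widens the spread within groups. These counts therefore do not show how many calls chance would give.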
